A study of Mus musculus with 8 samples.

How the data were processed

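RNA of whole mouse lung had been hybridised to Affymetrix mouse oligonucleotide arrays, 2 for each of 4 groups: C3H/HeJ in filtered air, C3H/HeJ in ozone, C3H/HeOuJ in filtered air and C3H/HeOuJ in ozone. Per the labels, the lungs were frozen in liquid nitrogen and RNA was extracted; an exposure of 72 h is stated for C3H/HeOuJ only. The replicates of a group carry the names 1a and 1b, which the labels do not explain. The deposited values are 1 intensity per probe set and array on a linear scale. The 2% trimmed mean of each array lay between 800.39 and 800.41, so the deposited intensity values had already been scaled to a common level; the software that made them is not given in the sources used here. Raw images were not analysed here.

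Of 12488 probe sets, 66 controls were set aside, leaving 12422. A floor was placed at the 20th percentile of all values, 69.63 (6.12 on the log2 scale); lower values were raised to it, and log2 was taken. Probe sets above the floor on at least 2 of 8 arrays were tested, 10953 in all, and 1469 dimmer ones were left out. Gene names came from an array annotation of 2016. It named 1 gene for 10833 probe sets, several for 396 and none for 1193. The probe sets tested covered 7629 genes, 1701 of them with more than 1 probe set.

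All 8 arrays entered 1 model of 4 group means in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend), which left 4 residual degrees of freedom and added 4.54 from the prior. The 6 comparisons were the ozone effect in each strain, their difference (the interaction), their mean, the strain difference in air and its mean over exposures. The p-values were adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. Standard errors are the moderated ones of the model; each fold change is C3H/HeOuJ over C3H/HeJ or ozone over air. A gene at the floor on every array of a group has only a lower bound of its change.

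Gene groups were 35 lists, each tested with camera in limma at its preset correlation of 0.01, with 1 probe set per gene (the one of highest mean) and adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. With the estimated correlation no list passed in any comparison; fry passed 2, 1, 1, 1, 2 and 7 lists in the 6 comparisons in the order given. In simulated data, a list of 30 genes shifted by 0.5 had an adjusted p of 5.1e-15 with the preset and 0.0686 with the estimated correlation. The simulated probe sets varied independently of each other, so this run could not show which setting is right for correlated genes.

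The comparisons, tests, gene lists, threshold, rule for named genes and most alternatives were chosen before the data were examined; the 5'/3' covariate and the array weights were added later. Genes were named by this rule. Among probe sets that passed and whose arrays did not overlap, the 10 largest rises and the 10 largest falls of a comparison were eligible, as were the 5 of smallest p where fewer than 5 passed. From each list up to 4 members past the threshold, or up to 2 of smallest p, were eligible. Another 14 genes were followed throughout where measured: Tlr4, Cd14, Nos2, Marco, Hspa1b, Cxcl2, Il6, Scgb1a1, Mt1, Mt2, Saa3, Lcn2, Chil3 and H2-Ea.

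RNA quality was read from the ratio of the 5' to the 3' intensity of the actin and Gapdh control probe sets. The model was tested on simulated data of 10953 probe sets, where it recovered 73.9% of 4-fold and 22.4% of 2-fold changes for the ozone effect in C3H/HeOuJ, and 34.4% and 8.33% for the interaction. For the 2 comparisons averaged over a factor it recovered 93.2% and 93.9% of 4-fold changes. Each run held many changed probe sets, which loosens the adjusted threshold, so these shares are too high where few probe sets change. Alternatives covered normalisation, floor, filter, variance model, arrays in the fit, replicate letters as blocks, threshold and leaving out each array. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15.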

Results

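Lung transcripts were measured in mice of 2 closely related C3H substrains that had breathed ozone or filtered air. C3H/HeJ mice carry a missense mutation of Tlr4, the endotoxin receptor, and respond poorly to endotoxin, whereas C3H/HeOuJ mice carry the intact gene. The series title names ozone and the leakiness of the airways as its subject. Each of the 4 combinations of strain and exposure was read on 2 oligonucleotide arrays, 8 arrays in all, and each array reported 12488 probe sets. The labels give an exposure of 72 h for C3H/HeOuJ only, and they give no ozone concentration. The median intensity of an array lay between 351 and 386, and 17.7% to 20.8% of the probe sets of a HeOuJ array lay below the floor of 69.6. The labels do not say that the arrays of a group came from separate animals, so every p-value measures only the spread between these arrays, which may be technical. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.30 for a comparison of 2 arrays with 2.

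In C3H/HeOuJ lungs, Reg3g, Saa3, Krt18 and Krt8 were higher in ozone than in air, and Hspa1a, Hspa1b and Hsp90aa1 were lower. Reg3g, which encodes an antibacterial lectin, rose from an intensity of 268 ± 25.6 in air to 1357 ± 62.6 in ozone (mean ± SD, 2 arrays each), a 5.08-fold rise with a log2 fold change of 2.34 (SE 0.21). Saa3, an acute phase serum amyloid, rose by a log2 fold change of 2.32 (SE 0.32), from 478 ± 114 to 2364 ± 279. Krt18 and Krt8, which pair in the filaments of simple epithelia, rose 3.18-fold and 1.99-fold. The RNAs of the inducible chaperones Hspa1a and Hspa1b and of Hsp90aa1 fell, with log2 fold changes of -2.16 (SE 0.26), -1.45 (SE 0.19) and -1.06 (SE 0.17). Hspa1a and Hspa1b were high in HeOuJ air (2028 and 2095) against HeJ air (394 and 437) and HeJ ozone (529 and 432). The same 2 HeOuJ air arrays therefore enter this fall, the strain difference in air and the interaction, which are not separate results.

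The comparison of ozone with air in C3H/HeOuJ gave 50 probe sets past an adjusted p of 0.05 in limma, 14 higher and 36 lower. The arrays of the 2 exposures did not overlap for any of the 50; this only describes them, since they were selected by their p in this comparison, and chance gives such a separation to 33.3% of unselected probe sets. Among the rises were also Pafah2, a lipase of oxidised phospholipids, which lay at the floor on both air arrays and rose at least 5.48-fold, Pstk, a kinase of selenocysteine synthesis, at 4.43-fold, and the unnamed transcript D17H6S56E-5 at 3.47-fold. Col9a1, Nhp2 and Nme2 rose 2.65-fold, 2.37-fold and 1.93-fold. The deepest named fall was that of Zfp281, a zinc finger repressor, from 769 ± 282 to 87.9 ± 46.3, with a log2 fold change of -3.02 (SE 0.48) and 1 ozone array at the floor. The noncoding RNA Tug1 fell with a log2 fold change of -2.17 (SE 0.29), the kinase substrate Marcks with -1.89 (SE 0.23) and the transcription factor Klf4 with -1.80 (SE 0.28). Cd47, Wnk1, Bcl6 and Eif4a2 fell with log2 fold changes of -1.77, -1.65, -1.45 and -1.37. Further probe sets of Pafah2 (0.28), Cd47 (-0.20) and Wnk1 (-0.29 and -0.31) moved less and did not pass. Tjp1, which encodes the tight junction scaffold ZO-1, fell from 6629 ± 29.5 to 2805 ± 208, a log2 fold change of -1.24 (SE 0.19), although a second, dimmer probe set of Tjp1 gave 1.25 with an adjusted p of 0.18. Chil3, a chitinase-like protein of alveolar macrophages, fell with a log2 fold change of -1.19 (SE 0.18). The adjusted p-values of these genes ran from 0.0105 for Reg3g and Wnk1 to 0.0497 for Nme2. Of the 43 genes called, 18 had a further tested probe set that did not pass, and for 13 of them every such probe set moved in the same direction, but for only 4 by at least 50% of the log2 change. The count of 50 fell to 0 when either HeOuJ ozone array, either HeOuJ air array or either HeJ ozone array was left out, and to 22 and 21 without HeJ air 1a and 1b. Without the filter on dim probe sets 48 passed, 24 higher and 24 lower, only 14 of them among the 50, and the count was 0 with only the 4 HeOuJ arrays in the fit, with a variance prior that did not follow intensity, or with the 5'/3' control ratio described next as a covariate. With that covariate the median went from 1.43 to 1.24 (median SE 0.41) for the 14 called higher and from -1.19 to -0.91 (median SE 0.34) for the 36 called lower. The change shrank for some genes, among them Zfp281 to -0.78 (SE 0.59), Klf4 to -0.85 (SE 0.49) and Tjp1 to -0.70 (SE 0.35). It was about as large for others, among them Reg3g at 2.655 (SE 0.44), Krt18 at 1.735 (SE 0.39) and Eif4a2 at -1.62 (SE 0.27).

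**Figure D1:**
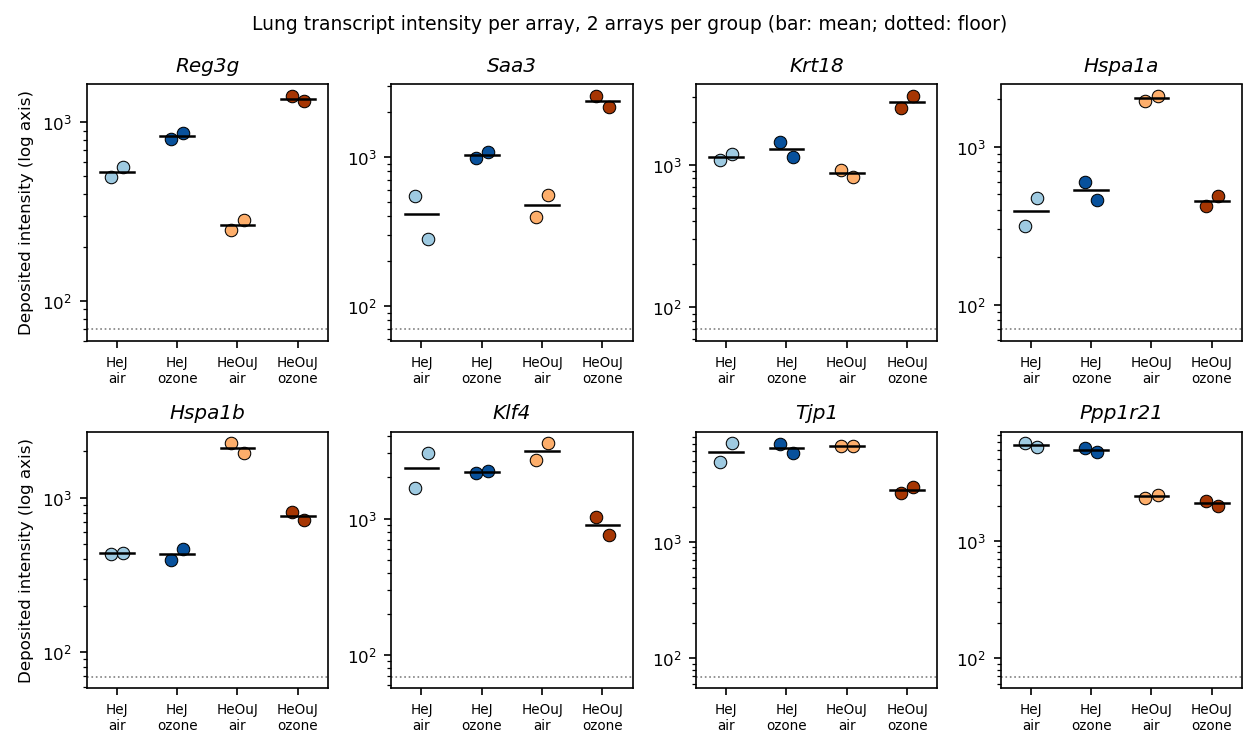
Deposited intensity (log axis) of 8 named genes on each of the 8 arrays, by strain and exposure; each point is an array, each bar the mean of 2 arrays and the dotted line the floor of 69.6. Reg3g, Saa3 and Krt18 are highest on the HeOuJ ozone arrays, Klf4 and Tjp1 are lowest there, Hspa1a and Hspa1b are highest in HeOuJ air, and Ppp1r21 is lower on all 4 HeOuJ arrays than on all 4 HeJ arrays.

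The 2 HeOuJ ozone arrays also stood apart in measures of the arrays themselves. The ratio of the 5' to the 3' control probe set of actin was 0.766 and 0.756 on them and 0.432 to 0.603 on the other 6 arrays, and that of Gapdh was 1.34 and 1.18 against 0.775 to 1.06. The ratio of a further control, the transferrin receptor, did not set these 2 arrays apart, at 0.490 and 0.289 against 0.184 to 0.518. Their first principal component scores, on the axis holding 30.7% of the variance, were 53.2 and 19.3, while the other 6 arrays scored at most 0.54. The 2 arrays had the lowest rank correlation of any replicate pair, 0.931, against 0.952 to 0.961 in the other 3 groups.

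**Figure D2:**
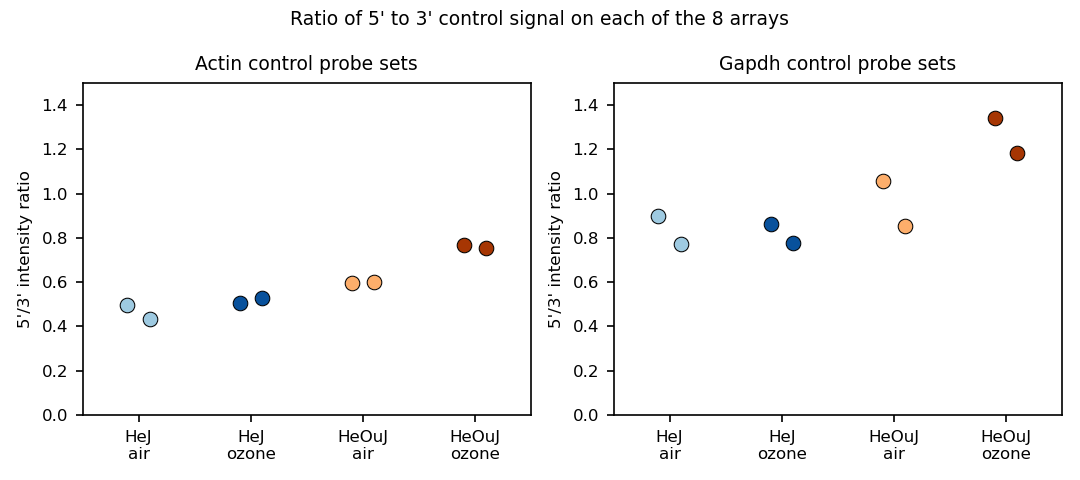
Ratio of the 5' to the 3' intensity of the actin (left) and Gapdh (right) control probe sets, with a point for each of the 8 arrays in the 4 groups. The 2 HeOuJ ozone arrays have the highest ratios, 0.766 and 0.756 for actin and 1.34 and 1.18 for Gapdh.

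Proliferation genes formed the group that rose with ozone in C3H/HeOuJ. Of 38 tested members of the cell cycle list, 30 were higher in ozone, with a median log2 fold change of 0.67, and the list passed limma's camera test with an adjusted p of 4.3e-05 over 35 lists (adjusted p = 0.185 with an estimated correlation). None of its members passed over all probe sets, and 10 passed, all higher, when adjusted over the list alone. Top2a, the topoisomerase of dividing cells, and Kif20a, a mitotic kinesin, were at the floor on both air arrays and had log2 fold changes of at least 1.75 and 2.34. A second probe set of Kif20a gave 0.33.

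The glucocorticoid response list and the extracellular matrix and protease list fell in C3H/HeOuJ. Of 16 glucocorticoid response genes 13 were lower (median -0.37, camera adjusted p 0.0125, adjusted p = 0.678 with an estimated correlation). None passed over all probe sets and 1 when adjusted over the list alone, Errfi1, a feedback inhibitor of the EGF receptor, at -0.53 (SE 0.11); the phosphatase Dusp1 had -0.48 (SE 0.14). Of 33 matrix genes 26 were lower (median -0.24, camera adjusted p 0.0125, adjusted p = 0.678 with an estimated correlation), none past the threshold over all probe sets and 2 lower and 1 higher when adjusted over the list alone. The collagen cross-linking enzyme Lox had -1.32 (SE 0.22, adjusted p 0.0505) and Col6a1 -0.87 (SE 0.17). Each of these 2 lists passed in 6 of the 8 fits that left out 1 array and lost its call without HeOuJ air 1b or HeOuJ ozone 1b, with adjusted p-values from 5.2e-04 to 0.302 for the glucocorticoid list and to 0.26 for the matrix list.

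Single members of other lists passed in C3H/HeOuJ while the lists as wholes did not. Of 24 heat shock and chaperone genes 17 were lower, 3 passed, all lower, and 4 lower and 2 higher passed when adjusted over the list alone (camera adjusted p 0.124). Of 15 acute phase genes 11 were higher, Saa3 passed, and 2 higher and 1 lower passed when adjusted over the list alone (camera adjusted p 0.414). Of 22 genes of tight and adherens junctions, the seals between epithelial cells, 10 were higher and 12 lower, only Tjp1 passed, and 2 passed, both lower, when adjusted over the list alone (camera adjusted p 0.699).

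Several genes followed in every comparison did not pass in C3H/HeOuJ. The endotoxin co-receptor Cd14 had a log2 fold change of 0.41 (SE 0.16), and the acute phase gene Lcn2 0.77 (SE 0.17). The metallothioneins Mt1 and Mt2 had 0.53 (SE 0.15) and 0.53 (SE 0.14). Il6 was at the floor on both air arrays and reached 117 ± 50.3 in ozone. The club cell secretoglobin Scgb1a1 had 0.48 (SE 0.29). The values of Cxcl2 (-0.10, SE 0.46), Nos2 (0.25, SE 0.66) and H2-Ea (0.05, SE 0.39) lay within their standard errors. The 22 tested genes of the TLR4 and NF-kB list had a median of 0.14 with 16 higher, and the list did not pass (camera adjusted p 0.81), with Vcam1 at -0.86 (SE 0.23) and Icam1 at 0.45 (SE 0.15). Tlr4 itself was not analysed here, and Marco was too dim to be tested.

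In C3H/HeJ lungs, the ozone effects that passed were those of groups of genes and not of single transcripts: proliferation genes were higher, and genes of B and plasma cells and of striated muscle were lower. Of the 38 cell cycle genes 31 were higher, with a median log2 fold change of 0.31 and a camera adjusted p of 1.8e-06 (adjusted p = 0.121 with an estimated correlation). Cks2, a subunit of cyclin-dependent kinases, and Cdc6, a licensing factor of DNA replication, had log2 fold changes of 1.42 (SE 0.38) and 1.47 (SE 0.41). Of 19 B and plasma cell markers 14 were lower (median -0.35, camera adjusted p 2.9e-06, adjusted p = 0.185 with an estimated correlation), and of 27 genes of cardiac and skeletal muscle 20 were lower (median -0.30, camera adjusted p 8.7e-04, adjusted p = 0.185 with an estimated correlation). The cell cycle, B and plasma cell and muscle lists each kept an adjusted p under 0.05 in all 8 fits that left out 1 array.

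No probe set passed an adjusted p of 0.05 in limma for ozone against air in C3H/HeJ. At an unadjusted p under 0.05 there were 476, against 548 given by chance among the 10953 tested. In simulated data of the same size and spread the same test recovered 71.0% of 4-fold changes and 21.2% of 2-fold changes. That run gave 59 calls in all, which loosens the adjusted threshold, whereas no real probe set passed. The recovered shares are thus too high for data in which few probe sets change. Most 2-fold changes would have been missed with these arrays, and 4-fold changes may have been missed too. The 5 named genes of smallest p, none of which passed, were the immunoglobulin light chain variable gene Igkv6-23 (-1.44, SE 0.17, adjusted p 0.136), the heavy chain genes Ighm (-1.03, SE 0.13) and Igha (-1.18, SE 0.17), the orphan nuclear receptor Nr4a1 (-0.88, SE 0.14) and the adrenergic receptor Adra2c (2.19, SE 0.36). Among the muscle genes the ventricular myosin light chain Myl2 had -1.47 (SE 0.26), with both ozone arrays at the floor, and the muscle cytochrome oxidase subunit Cox6a2 -0.57 (SE 0.16). None of the members of these 3 lists passed over all probe sets. Adjusted over the list alone, 3 B and plasma cell markers and 1 muscle gene passed, all lower, and no cell cycle gene did.

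MHC class II, macrophage and smooth muscle lists were also lower in C3H/HeJ ozone by camera, with adjusted p-values of 0.0377, 0.0389 and 0.0408 and medians of -0.25, -0.15 and -0.08. With an estimated correlation the adjusted p was 0.347, 0.514 and 0.504. No member of these 3 lists passed, over all probe sets or adjusted over the list alone. In all, 6 lists passed camera in C3H/HeJ, and 4 of them were left with quantile normalisation and 4 with the replicate letters as blocks. Of 22 macrophage markers 18 were lower, of 11 smooth muscle genes 9, and of 12 MHC class II genes 10, with H2-Eb1 at -0.45 (SE 0.15), H2-DMa at -0.40 (SE 0.14) and H2-Ea at -0.58 (SE 0.39). Chil3 had -0.62 (SE 0.18) and Saa3 1.39 (SE 0.32), the latter alone among 15 acute phase genes passing when adjusted over the list alone. Cd14 (0.06, SE 0.16), Mt1 (-0.13, SE 0.15), Hspa1b (-0.02, SE 0.19), Scgb1a1 (-0.22, SE 0.29) and Nos2 (0.46, SE 0.66) lay within their standard errors, and Mt2 (-0.19, SE 0.14), Cxcl2 (-0.65, SE 0.46) and Lcn2 (-0.31, SE 0.17) did not pass. Il6 was at the floor on all 4 HeJ arrays. With 1 array left out, the MHC class II list passed in 4 of 8 fits (adjusted p 0.0242 to 0.186), the macrophage list in 5 (0.027 to 0.462) and the smooth muscle list in 1 (0.0269 to 0.429), and all 3 lost their call without HeJ air 1a, HeJ ozone 1a or HeJ ozone 1b, and with the mean over a gene's probe sets (0.0659, 0.0501 and 0.0501).

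**Figure D3:**
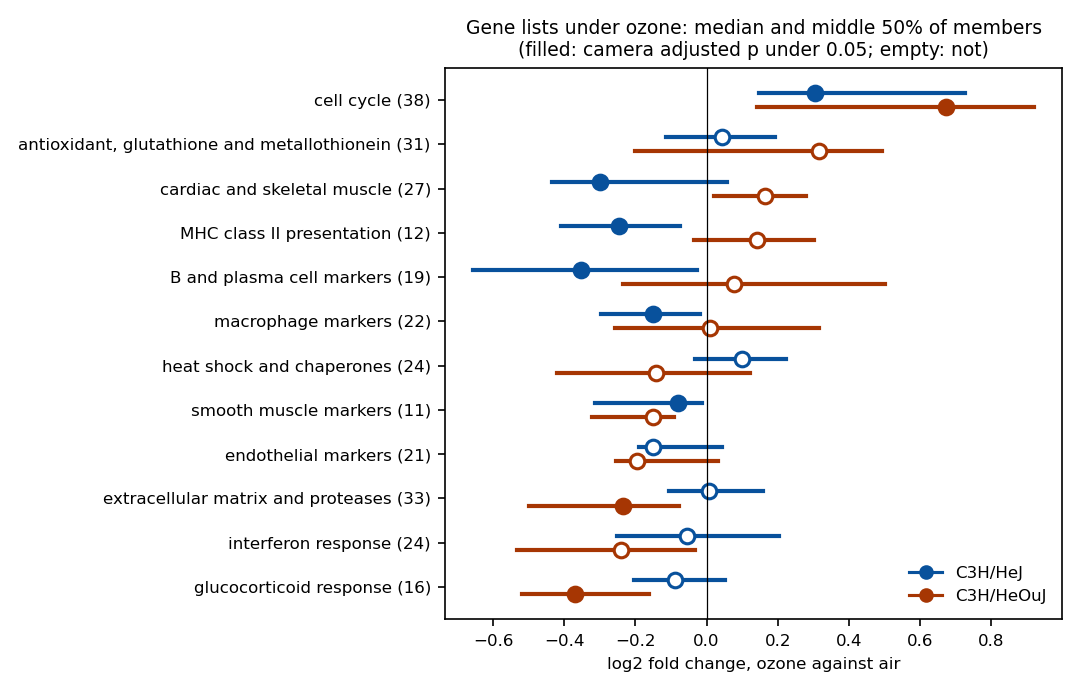
Median log2 fold change of ozone against air (points) and the middle 50% of the members (lines) for the 12 gene lists that passed camera in any of the 4 comparisons involving ozone, in C3H/HeJ (blue) and C3H/HeOuJ (brown); the number tested is in parentheses and filled points have a camera adjusted p under 0.05. The cell cycle list is higher in both strains, with medians of 0.31 and 0.67, and the B and plasma cell and the muscle list have medians of -0.35 and -0.30 in C3H/HeJ.

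The interaction asks whether ozone acted differently in the 2 strains. No probe set passed in limma; 1252 had an unadjusted p under 0.05, against 548 by chance. The smallest adjusted p, 0.0509, belonged to Wnk1 (-1.86, SE 0.20), Ighm (1.59, SE 0.18) and Eif4a2 (-1.66, SE 0.19), where a negative value means a lower ozone effect in C3H/HeOuJ. These 3 probe sets missed the threshold by a narrow margin. The count was 3 with quantile normalisation and 9 among probe sets above the median intensity. It stayed at 0 with median centring (smallest adjusted p in limma 0.128) and without a variance trend (0.215). It was also 0 with the replicate letters as blocks (0.0932) and with the 5'/3' ratio as a covariate (0.847). Hspa1a had -2.60 (SE 0.36, adjusted p 0.115) and Hspa1b -1.43 (SE 0.27, adjusted p 0.157). Saa3 had 0.93 (SE 0.45, adjusted p 0.489), so its response was not shown to differ.

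By gene list, 4 ozone effects differed between the strains in camera with 1 probe set per gene, and none did with the mean over a gene's probe sets (adjusted p 0.0648 for muscle and matrix, 0.0686 for B and plasma cells, 0.183 for heat shock). The B and plasma cell list (15 of 19 members with a higher effect in C3H/HeOuJ, median difference 0.57, adjusted p 0.0112) and the muscle list (20 of 27, 0.48, adjusted p 0.0121) had higher effects in C3H/HeOuJ. The extracellular matrix list (25 of 33 with a lower effect, -0.24, adjusted p 0.0244) and the heat shock and chaperone list (17 of 24, -0.19, adjusted p 0.0434) had lower effects there. Lox had -1.54 (SE 0.31) and Myl2 1.47 (SE 0.37), the latter with both HeOuJ groups and HeJ ozone at the floor. Adjusted over the list alone, 1 B and plasma cell marker passed with a higher effect, 1 matrix gene with a lower effect, and 1 chaperone with a higher and 5 with a lower effect. With an estimated correlation the adjusted p was 0.654 for the B and plasma cell, muscle and heat shock lists and 0.662 for the matrix list. With 1 array left out, the B and plasma cell list passed in 5 of 8 fits (adjusted p 9.6e-04 to 0.122), the muscle list in 6 (0.0044 to 0.0798), the matrix list in 2 (0.0031 to 0.283) and the heat shock list in 2 (0.0049 to 0.219). The cell cycle list did not pass in the interaction (camera adjusted p 0.412).

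Across the 10953 probe sets, the 2 strains' ozone effects had a Pearson correlation of -0.043 and a Spearman correlation of -0.055 over genes, which are not independent replicates, and 48.0% had the same sign. The 2 comparisons share no arrays. Of the 14 probe sets called higher in C3H/HeOuJ, 10 were positive in C3H/HeJ (median 0.22), and of the 36 called lower, 10 were negative there (median 0.20). At an unadjusted p under 0.05, 57 probe sets were higher in C3H/HeJ and lower in C3H/HeOuJ, against 20 for independent lists, and 22 were lower in C3H/HeJ and higher in C3H/HeOuJ, against 16.9. In the same direction, 27 were higher in both, against 20, and 31 lower in both, against 16.9. With a shared variance, a probe set of small variance is favoured in both lists. Each overlap can therefore exceed the value for independent lists without any relation between the strains' responses.

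Averaged over the strains, the clearest response to ozone was a higher level of proliferation genes. Of the 38 cell cycle genes 32 were higher, with a median log2 fold change of 0.52 and a camera adjusted p of 6.3e-10 (adjusted p = 0.055 with an estimated correlation), and 11 passed when adjusted over the list alone, none over all probe sets. Kif20a had 1.95 (SE 0.31), a lower bound since both HeOuJ air arrays and 1 HeJ air array lay at the floor, and Top2a 1.19 (SE 0.23). The list passed in all 8 fits that left out 1 array. Of the 38 genes, 25 were higher with ozone in both strains and 2 in neither. Since most of the 38 were higher in each strain, independent lists would give about this overlap. It does not show that the strains agreed gene by gene. Reg3g was the only named gene past the threshold over all probe sets, with a 2.84-fold rise (log2 fold change 1.51, SE 0.15, adjusted p 0.0359), higher on all 4 ozone arrays than on all 4 air arrays. A probe set with no gene name also rose, by 0.96 on the log2 scale. With the replicate letters as blocks no probe set passed in limma for averaged ozone, the smallest adjusted p being 0.064. The count of 2 fell to 0 on leaving out any of the 8 arrays and with the 5'/3' ratio as a covariate, where Reg3g kept a log2 fold change of 1.69 with a wider SE of 0.27.

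**Figure D4:**
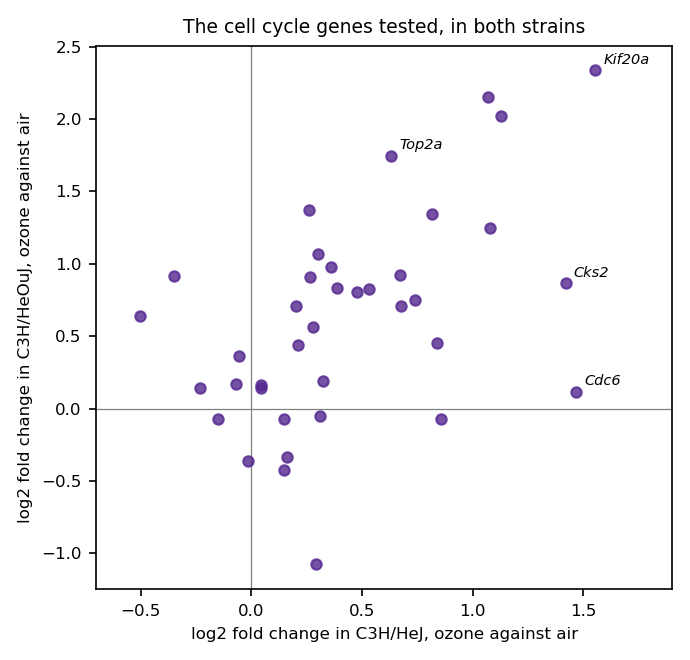
Log2 fold change of ozone against air in C3H/HeJ (horizontal axis) and C3H/HeOuJ (vertical axis) for the 38 tested genes of the cell cycle list, with a point for each gene. Of these, 25 lie in the upper right quadrant, higher with ozone in both strains, and 2 in the lower left, about as independent lists would give.

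Further lists passed camera for the average of both strains. Glucocorticoid response (median -0.26, 12 of 16 lower, adjusted p 0.0036), interferon response (-0.24, 19 of 24 lower, 0.0332), endothelial (-0.11, 16 of 21 lower, 0.0332) and smooth muscle genes (-0.17, 9 of 11 lower, 0.0451) were lower, and antioxidant, glutathione and metallothionein genes were higher (0.15, 21 of 31 higher, 0.0451). With an estimated correlation the adjusted p was 0.448 for the first 3 and the antioxidant list and 0.515 for smooth muscle. None had a member past the threshold over all probe sets; adjusted over the list alone, 2 glucocorticoid response genes passed lower, and 1 antioxidant gene passed in each direction. Errfi1 had -0.33 (SE 0.08). With 1 array left out, the glucocorticoid list passed in 6 of 8 fits (adjusted p 2.8e-04 to 0.0929), the interferon list in 4 (0.0070 to 0.173), and the endothelial, smooth muscle and antioxidant lists in 1 each (0.0023 to 0.274, 0.0174 to 0.206 and 0.0311 to 0.206); the endothelial list also lost its call with the mean over a gene's probe sets (0.0979).

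In filtered air, lungs of C3H/HeOuJ mice held more chaperone RNA than those of C3H/HeJ mice. Hspa1a lay at 2028 ± 94.9 in C3H/HeOuJ and 394 ± 111 in C3H/HeJ, a 5.24-fold difference (log2 2.39, SE 0.26, adjusted p 0.0249), and Hspa1b at 2095 ± 218 and 437 ± 2.94, a 4.78-fold difference (log2 2.26, SE 0.19, adjusted p 0.0055). Of 24 heat shock and chaperone genes 21 were higher in C3H/HeOuJ, with a median of 0.40, a camera adjusted p of 4.5e-11 (adjusted p = 0.131 with an estimated correlation), 2 past the threshold over all probe sets and 7 when adjusted over the list alone, all higher. The list passed in all 8 fits that left out 1 array. The mean 5'/3' ratio of the actin and Gapdh control probe sets was also higher in C3H/HeOuJ air than in C3H/HeJ air, 0.600 against 0.465 for actin and 0.955 against 0.836 for Gapdh. That of the transferrin receptor was not, at 0.186 and 0.211 on the HeOuJ air arrays against 0.269 and 0.518. With the actin and Gapdh ratio as a covariate no probe set passed, although the log2 difference was 2.89 (SE 0.41) for Hspa1a and 2.13 (SE 0.34) for Hspa1b, about as large with wider SEs. In ozone the difference of Hspa1a between the strains was -0.21 (SE 0.26) and that of Hspa1b 0.825 (SE 0.193).

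This strain comparison in air called 5 probe sets, 3 higher and 2 lower in C3H/HeOuJ. Ppp1r21, a protein of endosomal trafficking, lay at 2401 ± 92.3 in C3H/HeOuJ and 6579 ± 291 in C3H/HeJ (log2 -1.45, SE 0.12, adjusted p 0.0055). The probe set of Ighm with the highest mean had -1.51 (SE 0.13, adjusted p 0.0055), but the other Ighm probe sets went in both directions, 1 of them with 1.15. The fifth, a probe set with no gene name, was at the floor on the HeJ air arrays and had at least 2.60. Glucocorticoid response genes were higher in C3H/HeOuJ air (median 0.13, 14 of 16 higher, camera adjusted p 0.0036), 1 of them when adjusted over the list alone. MHC class II (-0.19, 9 of 12 lower, 0.0434), B and plasma cell (-0.34, 14 of 19 lower, 0.0432) and sex-linked genes (-0.46, 0.0434) were lower, with 3, 1 and 1 members passing when adjusted over the list alone, and with Eif2s3y, a Y-linked translation factor, at -1.09 (SE 0.21). Of the sex-linked genes, Kdm5d lay below the floor on every air array and had no measurable difference. The sex-linked list holds Y-linked genes and Xist, so its direction cannot be read as a sex difference. With an estimated correlation the adjusted p was 0.523 for each of these 4 lists. The HeJ air arrays also enter the fall of the MHC class II and B and plasma cell lists with ozone in C3H/HeJ. They enter the B and plasma cell interaction too, so these are not separate results. The same holds for the HeOuJ air arrays and the fall of the glucocorticoid list with ozone in C3H/HeOuJ. Over all 61 immunoglobulin probe sets the median strain difference in air was 0.014. The count of 5 fell to 0 on leaving out any of the 8 arrays or with only the 4 air arrays in the fit, and with 1 array left out the glucocorticoid list passed in 6 of 8 fits (adjusted p 2.4e-06 to 0.581, lost without HeJ air 1a or HeOuJ air 1b), the B and plasma cell list in 4 (0.0136 to 0.445), the sex-linked list in 3 (0.047 to 0.296) and the MHC class II list in 0 (0.0579 to 0.211); the B and plasma cell list also lost its call with the mean over a gene's probe sets (0.0505).

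Averaged over both exposures, C3H/HeOuJ lungs had higher RNA of chaperones and of macrophage genes. Cd68, a lysosomal glycoprotein of macrophages, was 1.92-fold higher (log2 0.94, SE 0.13), and of 22 macrophage markers 14 were higher (median 0.16, camera adjusted p 0.0045, adjusted p = 0.452 with an estimated correlation), 1 past the threshold over all probe sets and 7 when adjusted over the list alone. Of the 24 heat shock and chaperone genes 20 were higher (median 0.27, camera adjusted p 2.4e-06, adjusted p = 0.351 with an estimated correlation), with Hspa1b at 2.91-fold, the only member past the threshold over all probe sets, and 10 higher and 1 lower when adjusted over the list alone. The log2 difference of Hspa1b was 2.26 in air and 0.825 (SE 0.193) in ozone, and that of Hspa1a 2.39 and -0.21 (SE 0.26). For these 2 genes the average thus rests largely on the air arrays. Lcn2, an iron-sequestering acute phase protein, was 1.92-fold higher, and 12 of 15 acute phase genes were higher (median 0.30, camera adjusted p 0.0427, adjusted p = 0.452 with an estimated correlation), 3 higher and 1 lower when adjusted over the list alone.

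This comparison called 17 probe sets, 11 higher and 6 lower in C3H/HeOuJ, and for 15 of them the 4 arrays of each strain did not overlap; this only describes them, since they were selected by their p in this comparison, and chance gives it to 2.86% of unselected probe sets. Ppp1r21 was lower in both exposures (log2 -1.48, SE 0.09, adjusted p 0.0008). Eif2s3y (-1.74, SE 0.15), Cystm1 (-1.40, SE 0.14) and Skap2, an adaptor of leukocyte adhesion (-1.21, SE 0.14), were lower too. Fabp1, a fatty acid binding protein, was 3.34-fold higher (a second probe set had a log2 difference of -0.18), Nme2, a nucleoside diphosphate kinase, 1.99-fold, Igha 1.94-fold and the ribosome assembly factor Sbds 1.71-fold. Ighm was called in both directions by 2 probe sets, 1.74 and -0.72. The lower one had -1.51 in air, but in ozone it lay at 3740 ± 432 in C3H/HeOuJ and 3546 ± 90.3 in C3H/HeJ. The sex-linked list was lower (median -0.76, 3 of 4 lower, camera adjusted p 0.0289, adjusted p = 0.452 with an estimated correlation), with 2 members lower when adjusted over the list alone. This list holds Y-linked genes and Xist, so its direction cannot be read as a sex difference. With 1 array left out the heat shock list passed in all 8 fits, the macrophage list in 7 (adjusted p 0.0027 to 0.0624), the sex-linked list in 4 (0.0334 to 0.0907) and the acute phase list in 1 (0.0431 to 0.633); the acute phase list also lost its call with the mean over a gene's probe sets (0.17). The count of 17 fell to between 1 and 2 for 7 of the 8 arrays left out and was 15 without the other, HeOuJ air 1b, and it was 0 with the 5'/3' ratio as a covariate. There the log2 difference stayed about as large, with wider SEs, for Ppp1r21 at -1.63 (SE 0.28), Hspa1b at 1.35 (SE 0.46) and Eif2s3y at -1.48 (SE 0.50), but shrank for Nme2 from 0.99 to 0.33 (SE 0.27), for Lcn2 from 0.94 to 0.51 (SE 0.38) and for Fabp1 from 1.74 to 0.92 (SE 0.72). It shrank also for Sbds from 0.77 to 0.41 (SE 0.33) and for the higher Ighm probe set from 1.74 to 0.74 (SE 0.42). It grew for Cystm1 from -1.40 to -2.44 (SE 0.28) and for Skap2 from -1.21 to -1.94 (SE 0.38).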

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

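The tests of replicate arrays for RNA quality, of a response shared by the strains and of a constant strain difference were chosen only after the result was seen, as was the 5'/3' covariate.

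The interaction of strain and ozone, a test of the difference itself, passed camera at its preset correlation for 4 gene lists: B and plasma cell markers (adjusted p 0.0112), cardiac and skeletal muscle (0.0121), extracellular matrix and proteases (0.0244) and heat shock and chaperones (0.0434). With an estimated correlation none of the 4 passed (adjusted p 0.654, 0.654, 0.662 and 0.654), with the mean over a gene's probe sets none passed either (0.0686, 0.0648, 0.0648 and 0.183), and with 1 array left out they passed in 5, 6, 2 and 2 of 8 fits. The actin and Gapdh control probe sets, which no comparison uses, stood above the other groups on the HeOuJ ozone arrays, with a mean 5'/3' ratio of 0.761 for actin, against 0.465 to 0.600, and of 1.26 for Gapdh, against 0.820 to 0.955. The ratio of the transferrin receptor control did not stand apart there.

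Pattern A is the fall of 36 of the 50 probe sets called with ozone in C3H/HeOuJ, on the 2 arrays with the highest 5'/3' ratios; without the filter on dim probe sets the calls were 24 higher and 24 lower, 14 of them among the 50. After removing a trend on genomic span the median was -1.21 (SD 0.49), against -1.22 before. This could not decide on gene length. The trend over all probe sets was weak (Spearman correlation -0.104), the 36 had been chosen by their falls, and genomic span is not transcript length. In C3H/HeJ the same probe sets had a median of 0.196 (bootstrap interval over probe sets 0.032 to 0.252), against -1.19 in C3H/HeOuJ. The interval leaves out the spread between arrays, and between the HeJ air arrays these probe sets differed by a median of -0.306. The choice of the 36 by their falls also favours a large median in C3H/HeOuJ, but not in C3H/HeJ. The values argue against a shared fall as large as -1.19, but a smaller shared fall stays open. RNA quality or labelling stays open: between the HeJ air replicates, whose 5'/3' ratios differ most, 29 of the 36 were lower on 1a than 1b, with a median of -0.306, below all 10000 random lists matched on expression, but the medians within the other groups were 0.005, 0.003 and -0.025, inside the range of such lists. With the 5'/3' ratio as a covariate the median went from -1.19 (median SE 0.17) to -0.91 (SE 0.34) and no call was left, the change being smaller and its SE about doubled; the ratio separates the HeOuJ ozone from the HeOuJ air arrays, so an effect of ozone and one of RNA handling may both contribute.

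Pattern B is the higher Hspa1a and Hspa1b in C3H/HeOuJ air. The other 22 chaperones had a median of 0.36, with 19 higher (unadjusted camera p 1.0e-08, and 0.00736 with an estimated correlation). Higher levels were thus not limited to these 2 genes. The shift was read on the same arrays and is far smaller than the 2.39 of Hspa1a and the 2.26 of Hspa1b. It therefore cannot decide whether a hybridisation difference contributed to these 2 values. A constant strain difference of the size seen in air is argued against by the smaller differences in ozone given below. The interaction was -2.60 for Hspa1a (95% interval -3.43 to -1.77) and -1.43 for Hspa1b (-2.05 to -0.81), although neither passed over all probe sets. It uses the same air arrays by which the 2 genes were picked. That selection favours a large interaction, and the intervals do not allow for it. Stress of the animals or handling of the HeOuJ air lungs before freezing was not tested and stays open, as does a difference between the strains that ozone lowers. In ozone the difference was -0.21 (SE 0.26) for Hspa1a and still 0.825 (SE 0.193) for Hspa1b.

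Pattern C is the lower B and plasma cell list with ozone in C3H/HeJ. A lower share of B cells cannot be told apart from lower immunoglobulin RNA per cell: the 15 markers other than immunoglobulins had a median of -0.235 (bootstrap interval -0.637 to 0.032), the 4 immunoglobulin genes one of -0.691, and the interval of the difference, -1.061 to 0.336, included 0. Less lymphoid tissue in the HeJ ozone samples stays open too, since the 23 T and NK cell genes had a median of -0.075 with an interval of -0.249 to 0.082. Of 61 immunoglobulin probe sets, 51 were lower with ozone in C3H/HeJ (50 with quantile normalisation, 51 with median centring) and 24 in C3H/HeOuJ.

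Other ways to split the 8 arrays into 4 and 4 tested the 2 averaged comparisons. For ozone, 2 of 35 splits gave at least 2 calls: the real one, with 2, and the split by strain, the other factor of the design, with 11. For strain, 2 of 35 gave at least 17: the real one, with 17, and 1 other, with 70, which put HeJ air 1a and HeOuJ air 1a with both HeOuJ ozone arrays. These 4 arrays had the highest Gapdh 5'/3' ratios, 0.897 to 1.34, against at most 0.864 on the others. They also had the highest first principal component scores. Actin did not order them so, with 0.498 on HeJ air 1a and 0.603 on HeOuJ air 1b. This split thus follows a structure of the arrays and is not a random grouping. All other splits gave 0 calls in both comparisons. With 2 of 35 splits, the real one counted, this count does not exclude chance for either comparison.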

How the results depend on the processing

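The fits with the 5'/3' ratio as a covariate and with array weights were chosen only after the result was seen. Counts of calls are given for ozone in C3H/HeJ (0 as reported), ozone in C3H/HeOuJ (50), the interaction (0), ozone averaged over strains (2), strain in air (5) and strain averaged over exposures (17), where they moved by more than 1.5 times or, in C3H/HeOuJ without a filter, where the probe sets called changed. Quantile normalisation gave 3 for the interaction; median centring gave 1 for averaged ozone and 8 for strain in air. A floor at the 10th percentile gave 3 for the interaction and 5 for averaged ozone, a floor at the 40th percentile 113 for C3H/HeOuJ and 3 for the interaction, and no floor 110, 9, 10 and 9 for C3H/HeOuJ, the interaction, averaged ozone and strain in air. Without a filter the counts were 8 in C3H/HeJ, 48 in C3H/HeOuJ (24 higher and 24 lower, 14 of the 48 shared with the 50), 10 for the interaction, 14 for averaged ozone, 11 for strain in air and 40 for averaged strain; above the median intensity they were 1, 172, 9, 10 and 8 in C3H/HeJ, C3H/HeOuJ, the interaction, averaged ozone and strain in air. Without a variance trend they were 0 in C3H/HeOuJ, 0 for averaged ozone, 3 for strain in air and 7 for averaged strain; at an adjusted p under 0.01 they were 0, 0, 3 and 5; with a 2-fold limit 1 for averaged ozone and 10 for averaged strain. With only the 4 arrays compared they were 0 in C3H/HeOuJ and 0 for strain in air. The covariate gave 0 in C3H/HeOuJ, averaged ozone, strain in air and averaged strain; array weights gave 2 in C3H/HeJ, 6 in C3H/HeOuJ, 0 for averaged ozone and 9 for strain in air. Leaving out each array gave 0 to 22 in C3H/HeOuJ, 0 to 0 for averaged ozone, 0 to 0 for strain in air and 1 to 15 for averaged strain. The cause was not tested.

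Whether the letters a and b pair the samples was not settled: deviations from the group means of arrays with the same letter had correlations of 0.117, 0.138 and 0.109 among the 3 groups other than HeOuJ ozone, and of 0.005, -0.01 and 0.036 between these and HeOuJ ozone. The Gapdh 5'/3' ratio was higher on 1a than on 1b in all 4 groups, that of actin in 2. With the replicate block by letter the count was 57 in C3H/HeOuJ, 0 for averaged ozone and 29 for averaged strain, 17 of the 29 shared with the count as reported, and 2, 3 and 2 lists passed for averaged ozone, strain in air and averaged strain; the block moved no other count by more than 1.5 times.

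Of the lists, 6, 3, 4, 6, 5 and 4 passed in the 6 comparisons in the order above, and 0 with an estimated correlation in each. The mean over a gene's probe sets gave 3 in C3H/HeJ and 0 for the interaction. Leaving out each array gave 3 to 5 lists in C3H/HeJ, 1 to 5 in C3H/HeOuJ, 0 to 3 for the interaction, 1 to 5 for averaged ozone, 2 to 4 for strain in air and 1 to 4 for averaged strain. The correlation of the strains' ozone effects was -0.043 as reported, -0.044 with quantile normalisation, -0.070 above the median intensity and -0.121 to 0.062 with 1 array left out.

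Among genes named, the sign of a change turned with 1 array left out for Hspa1b in C3H/HeJ (-0.133 to 0.091, turned without HeJ ozone 1a) and Nos2 in C3H/HeJ (-0.112 to 1.022, turned without HeJ air 1b). In C3H/HeOuJ it turned for Cxcl2 (-0.683 to 0.485, turned without HeOuJ air 1a, and 0.089 without HeOuJ ozone 1b), H2-Ea (-0.459 to 0.567, turned without HeOuJ air 1a, and -0.032 without HeOuJ ozone 1a) and Nos2 (-0.795 to 1.296, turned without HeOuJ ozone 1a). Cxcl2 turned also with the floor at the 10th percentile (0.507) and with no floor (0.42), and Nos2 (-1.7) and Scgb1a1 (-0.374) in C3H/HeOuJ with the covariate. None of these had passed. Of the other values of named genes, outside the fits that left out an array 204 were weaker, 37 stronger and 1225 the same; in the fits that left out an array 291 were weaker, 0 stronger and 518 the same.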

Other observations

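No test in this part was chosen only after the result was seen, although the values per array of the sex-linked genes were looked at because Eif2s3y had passed.

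Antioxidant genes went in both directions in C3H/HeOuJ ozone. Of 31 members of the antioxidant, glutathione and metallothionein list 19 were higher and 12 lower (median 0.32, camera adjusted p 0.11), none passed over all probe sets, and 5 passed higher and 2 lower when adjusted over the list alone. The glutathione transferase Gsto1 had 0.77 (SE 0.15, adjusted p 0.0695) and Gclm, a subunit of the enzyme that starts glutathione synthesis, 0.82 (SE 0.18, adjusted p 0.0939).

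Inflammatory genes did not pass as a group in C3H/HeOuJ ozone. Of 26 cytokines and chemokines 16 were higher (median 0.11, camera adjusted p 0.699), with 1 higher and 2 lower when adjusted over the list alone; Tnf had 1.46 (SE 0.30) and Ccl9 -1.21 (SE 0.26), and neither passed over all probe sets. Of 18 neutrophil markers 11 were higher (camera adjusted p 0.935), with S100a8 at -0.72 (SE 0.16) and Itgam, at the floor on both air arrays, at 1.24 (SE 0.34).

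Eif2s3y, a Y-linked gene, lay at 900 to 1337 on the 4 HeJ arrays, at 455 and 467 in HeOuJ air and at 233 and 246 in HeOuJ ozone. Xist, which is transcribed from the inactive X chromosome of females, lay at 83.7 and 100 in HeJ air, 82.3 and 36.8 in HeJ ozone, 16.3 and 72.6 in HeOuJ air and 132 and 160 in HeOuJ ozone. With ozone in C3H/HeOuJ, Xist was higher (log2 fold change 1.03, SE 0.29) and Eif2s3y lower (-0.95, SE 0.21) when adjusted over the sex-linked list alone, and neither passed over all probe sets. The labels do not give the sex of the mice.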
